A study of Mus musculus with 11 samples.

How the data were processed

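Gene expression in adventitia of the mouse abdominal aorta was read on 11 Affymetrix arrays, 4 of ATLO adventitia and 4 of outside-lesion adventitia of Apoe-deficient mice and 3 of wild-type mice. Per the labels' protocols, the tissue was microdissected with a laser from frozen sections and taken up in Trizol. RNA of the Apoe-deficient samples was extracted with phenol and chloroform and an RNeasy Micro kit and amplified by in vitro transcription for 68 h, and RNA of the wild-type samples was extracted with an RNeasy Lipid Tissue kit and amplified for 24 h. The deposited values are linear signal intensities per probe set, and per the submitters' processing notes the authors used GCOS 1.4. The deposited intensities had a mean of 500 per array after trimming 2% of probe sets at each end (500.2 on average, between 500.168 and 500.266), so each array had been scaled to a common level before deposit. Detection calls were not used here, and the summary method beyond the tool's name is not given in the sources used here. Median signals per array lay between 151.5 and 191, and the signal has no count behind it, so the number of arrays sets the precision.

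The table held 22690 probe sets, of which 64 controls were left out. Genes were named from the platform annotation, in which 20380 of the remaining 22626 probe sets had 1 gene symbol, 691 had several and 1555 had none; only those with 1 symbol were named. The others were tested and counted, and some of the largest changes are among them. Gene IDs of 20351 of these were found in the mouse RefSeq gene table, and no symbol had to be updated. No coordinates are given, because no genome build is named in the files. Ccl21a, which was to be reported in any case, had only a probe set shared with other genes, so it was not analysed here.

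Signals were used as scaled by the authors, raised to a floor of 35.1 (the 20th percentile of all values) and taken to log2. Folds of probe sets near the floor are therefore understated, and a group wholly at the floor gives a lower bound. A probe set was tested where at least 3 arrays lay above their own 40th percentile, which kept 14988. A model with a mean per group was fitted to all 11 arrays with limma 3.58.1 in R 4.3.3, with an intensity trend in the variance prior, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. Errors of log2 changes are standard errors, and errors of signals are SD. For gene lists, the probe set with the highest mean represented each of 9055 genes, and camera was run with a preset correlation of 0.01 on 26 of 27 lists with at least 5 measured genes. The erythroid list was left out because only Alas2 and Slc4a1 were measured, neither of them called in any comparison. No camera call held with a correlation estimated from the data, and that p is given beside each called list. Lists overlap in part, and genes of a list are not independent. An exact two-sided permutation test of the mean log2 value of a list per array, with the same adjustment, was added after seeing the data. With 35 splits its smallest p is 0.0286, so a list passes only where at least 15 of the 26 lists reach that p, and lists pass or fail together.

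The groups, tests, lists, alternatives and the rule for named genes were set before the data were examined. For each comparison the rule named the 8 genes with the largest rise and the 8 with the largest fall among genes that were called, did not overlap between the groups' arrays and lay above the 40th percentile of all values (108.4) in the higher group. It also named the 2 called members with the largest change of each called list, and Apoe, Cxcl13, Cd3e, Th, Acta2 and Adipoq in all cases. Genes said to be named after their values were seen fall outside the rule, as do uncalled or further list members in the closing section and the genes drawn in the figure of neuron genes. No probe set of a named gene was called in the opposite direction to the one reported.

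The fit was tested on simulated data with 100 of 14988 probe sets changed 2-fold and 100 changed 4-fold. It recovered 57% and 89% for ATLO against outside-lesion, 40% and 87% for ATLO against wild type, and 41% and 83% for outside-lesion against wild type, with 8, 10 and 15 false calls among 14788 unchanged probe sets. Fewer probe sets were changed than were called in the data (31.9%, 26.8% and 3.26% of those tested), and the simulated noise was independent. These rates need not hold for the real fits. In simulated lists of 20 probe sets, 20 of 20 lists shifted by 0.5 on the log2 scale were called in each comparison and 0 of 20 unchanged lists, but the simulated genes were uncorrelated. Alternatives were quantile normalization, equal array medians, other floors, other filters, only the compared groups, the replicate number as a block, array weights, no intensity trend, a 2-fold threshold, all probe sets of a gene averaged, an estimated correlation and each array left out in turn. The actin 3' to 5' ratio as a covariate was added after seeing the data. Figures were drawn with matplotlib 3.10.9.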

Results

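Gene expression was measured with Affymetrix arrays in the adventitia, the outer connective tissue layer of the artery wall, of the abdominal aorta of male mice aged 78 weeks. The tissue was cut out of frozen sections with a laser, and 11 arrays were made. Of these, 4 came from mice lacking apolipoprotein E (Apoe), which carry atherosclerotic lesions at this age, from adventitia inside the lesion area that held artery tertiary lymphoid organs (ATLO, aggregates of lymphocytes in the adventitia of diseased arteries). Another 4 came from Apoe-deficient adventitia outside the lesion area, and 3 came from wild-type mice. The titles of the wild-type arrays also carry the letters PNS, which the other titles lack and no label explains, so whether their dissection differed is not given. For the Apoe-deficient arrays, each sample pooled 200 sections of 10 micrometres, and the aorta had been removed together with neighbouring lymph nodes, fat and connective tissue. The tissue label places the second group outside the lesion area, whereas the series' design text calls it mice without lesions. It is called outside-lesion adventitia here. Because ATLO adventitia was dissected for containing lymphoid aggregates, a higher level of lymphocyte genes there partly follows from the choice of tissue. No label says that arrays of a group came from separate animals, so p-values measure only the spread between these samples, which may be technical. They would be too small if arrays shared an animal. The number of arrays limits the precision.

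Apoe, the gene disrupted in the mutant mice, was read at a signal of 12417 ± 651 (SD, n = 3) in wild-type adventitia. Its signal was 134 ± 31.1 (SD, n = 4) in ATLO adventitia and 110.0 ± 67.0 (SD, n = 4) outside the lesion, so that all 11 arrays matched their genotype label. Against wild type, Apoe was lower by limma in ATLO (log2 change -6.57 ± 0.41, adjusted p = 1.97e-06) and outside the lesion (log2 change -7.05 ± 0.41, adjusted p = 2.15e-06), and the difference between the mutant groups did not pass the test (log2 change 0.48 ± 0.38, adjusted p = 0.363). Pearson correlations of log2 signals across probe sets, which are not independent replicates, lay between 0.933 and 0.965 for pairs of ATLO arrays, 0.925 and 0.960 for outside-lesion pairs and 0.938 and 0.947 for wild-type pairs. Between groups they lay between 0.804 and 0.893 for ATLO against outside-lesion arrays, 0.804 and 0.894 for ATLO against wild type, and 0.904 and 0.932 for outside-lesion against wild type. The 3' to 5' signal ratio of the actin control, which rises as RNA degrades, was 4.61 ± 2.71 (SD, n = 4) in ATLO, 8.71 ± 2.83 (n = 4) outside the lesion and 4.98 ± 0.683 (n = 3) in wild type. None of its differences passed an exact two-sided permutation test over arrays (p = 0.114 for ATLO against outside-lesion, 0.657 for ATLO against wild type and 0.0857 for outside-lesion against wild type, with 0.0286 the smallest p possible).

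The comparison of ATLO with outside-lesion adventitia asked how adventitia with lymphoid aggregates differed from adventitia of the same genotype away from the lesions. Most measured genes of B cells, plasma cells, T cells and macrophages were higher in ATLO, and most of fat cells and of mitochondrial respiration were lower. None of these 6 lists was called by camera with an estimated correlation (adjusted p between 0.154 and 0.351). Pou2af1, a B cell transcriptional coactivator, had a signal of 5557 ± 1783 (SD, n = 4) in ATLO and 281 ± 121 (n = 4) outside the lesion (log2 change 4.37 ± 0.75, adjusted p = 6.49e-04). Cxcl13, the chemokine that draws B cells into follicles, was read at 4629 ± 549.5 against 870.1 ± 263 (log2 change 2.46 ± 0.25, adjusted p = 2.20e-05). Cidea, a lipid droplet protein of brown fat, was read at 689 ± 273 against 12337 ± 6509 (log2 change -3.95 ± 0.50, adjusted p = 7.95e-05). In all, limma called 4777 of 14988 probe sets at a Benjamini-Hochberg adjusted p under 0.05, with 2688 higher and 2089 lower in ATLO. Counted by genes with a representing probe set, 1791 of 9055 were higher and 1351 lower.

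Among named genes without overlap between the arrays of the groups, those with the largest rise in ATLO by limma with Benjamini-Hochberg adjustment began with 2 immunoglobulin light chain probe sets. These were Igk (log2 change 4.53 ± 0.74, adjusted p = 4.46e-04) and Iglv1 (log2 change 4.52 ± 0.77, adjusted p = 6.01e-04). Immunoglobulin genes are so alike that their probe sets can read related transcripts, and another Igk probe set had a log2 change of -0.26 and another of Iglv1 2.04. Mmp12, the macrophage elastase (log2 change 4.45 ± 0.50, adjusted p = 3.59e-05), Saa3, an acute-phase serum amyloid (log2 change 4.44 ± 0.64, adjusted p = 1.80e-04), and Slpi, a secreted protease inhibitor (log2 change 4.41 ± 1.09, adjusted p = 0.00738), followed. Frzb, a secreted Wnt antagonist, was 877 ± 150.4 in ATLO and 41.8 ± 34.4 outside the lesion (log2 change 4.23 ± 0.29, adjusted p = 4.10e-06). Cd3d, a chain of the T cell receptor complex, had a log2 change of 3.93 ± 0.51, adjusted p = 9.36e-05. Separation of all arrays by group held for 4558 of the 14988 probe sets (30.4%), where chance would give 2.86%.

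Of the immune lists fixed beforehand, 13 of 14 measured B cell markers rose (14 adjusted over the list alone), with a median log2 change of 2.67 (camera adjusted p = 2.05e-06, and adjusted p = 0.351 with an estimated correlation). Cd79a, part of the B cell receptor, rose (log2 change 3.11 ± 0.55, adjusted p = 7.76e-04). Among plasma cell markers, 9 of 11 rose (10 adjusted over the list alone; camera adjusted p = 3.62e-04, and adjusted p = 0.192 with an estimated correlation), including the endoplasmic reticulum proteins Creld2 (2.99) and Derl3 (2.79), given as log2 change. For T cell markers, 15 of 16 rose (15 adjusted over the list alone; camera adjusted p = 2.39e-07, and adjusted p = 0.192 with an estimated correlation). Il7r, the interleukin 7 receptor, was 1562 ± 255 against 167 ± 57.9 (log2 change 3.27 ± 0.27, adjusted p = 1.11e-05). Cd3e was 351 ± 93.4 against 88.3 ± 74.9 (log2 change 2.25 ± 0.52, adjusted p = 0.00504). Of 15 genes of lymphoid organ formation, 9 rose (11 adjusted over the list alone; camera adjusted p = 4.21e-05, and adjusted p = 0.154 with an estimated correlation). Ltb, encoding lymphotoxin beta, rose by a log2 change of 3.18 ± 0.48 (adjusted p = 2.62e-04). Ccr7, the receptor that guides T cells and dendritic cells, had a signal of 209 ± 46.8 in ATLO and lay at the floor on all outside-lesion arrays. Its log2 change of 2.54 (adjusted p = 4.69e-05) is a lower bound.

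Of 19 macrophage markers, 17 rose, and as many when adjusted over the list alone (camera adjusted p = 7.26e-09, and adjusted p = 0.192 with an estimated correlation). Mpeg1, which encodes the pore-forming protein perforin-2, was 6114 ± 644 against 922 ± 131 (log2 change 2.73 ± 0.14, adjusted p = 3.36e-07). Ctss, a lysosomal protease, rose by a log2 change of 2.33 (adjusted p = 3.42e-05). In the list for antigen presentation by MHC class II, 11 of 13 rose, with 11 adjusted over the list alone (camera adjusted p = 4.12e-07, and adjusted p = 0.154 with an estimated correlation), among them H2-Oa (2.75) and the dendritic cell integrin Itgax (2.45). Of 18 interferon response genes, 9 rose (10 adjusted over the list alone; camera adjusted p = 3.62e-04, and adjusted p = 0.154 with an estimated correlation). The chemokine Cxcl10 (3.02) and Mx1 (1.99) changed most. Of 11 complement genes, 7 rose (7 adjusted over the list alone; camera adjusted p = 0.00269, and adjusted p = 0.355 with an estimated correlation), including C3ar1 (1.83) and C1ra (1.46). Most proliferation genes went the same way. Of 19 in the cell cycle and germinal centre list, 15 rose, 15 adjusted over the list alone (camera adjusted p = 7.57e-05, and adjusted p = 0.380 with an estimated correlation). Mki67 was 924 ± 435 against 124 ± 67.7 and Top2a 548 ± 153 against 149 ± 94.0. In the fibroblast and extracellular matrix list, 9 of 22 rose (10 adjusted over the list alone; camera adjusted p = 0.00163, and adjusted p = 0.521 with an estimated correlation), led by the proteoglycan lumican, Lum (2.75), and the collagen gene Col5a2 (1.82).

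Most measured genes of fat and respiration fell in ATLO. All 27 measured genes of oxidative phosphorylation were lower, with a median log2 change of -1.60 (27 adjusted over the list alone; camera adjusted p = 1.17e-19, and adjusted p = 0.192 with an estimated correlation). Cycs, cytochrome c, was 4927 ± 1185 against 22050.4 ± 6577 (log2 change -2.13 ± 0.24, adjusted p = 3.51e-05). Cyc1, cytochrome c1, was 3027 ± 486 against 13915 ± 4898 (log2 change -2.12 ± 0.27, adjusted p = 7.59e-05). Of 19 adipocyte genes, 18 fell (19 adjusted over the list alone; camera adjusted p = 6.22e-12, and adjusted p = 0.154 with an estimated correlation). Ucp1, the uncoupling protein of brown fat, was 344 ± 386 against 18351 ± 12451 (log2 change -5.45 ± 1.58, adjusted p = 0.0177). Outside-lesion replicate 2 read it at 143 where the other 3 lay between 20513 and 26624. Adipoq, which encodes the fat hormone adiponectin, was 12671 ± 3446 against 33422 ± 4733 (log2 change -1.43 ± 0.22, adjusted p = 2.88e-04). Among genes without overlap between the groups, the largest falls were those of the fatty acid transporter and ligase Slc27a2 (log2 change -4.23 ± 0.97, adjusted p = 0.00476) and Cidea. They were followed by the fatty acid-sensing receptor Ppara (log2 change at least -3.68 in size, since all ATLO arrays lay at the floor, adjusted p = 1.05e-04), Pdk4 (-3.43), Cox8b (-3.37), Coq8a (-3.22), Pank1 (-3.14) and Kcnk3 (-3.04). Pdk4 is the kinase that restrains glucose oxidation, Cox8b a subunit of cytochrome oxidase, Coq8a a kinase-like protein of coenzyme Q synthesis, Pank1 a pantothenate kinase and Kcnk3 a potassium channel. Another probe set of Coq8a was at -1.52.

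**Figure D1:**
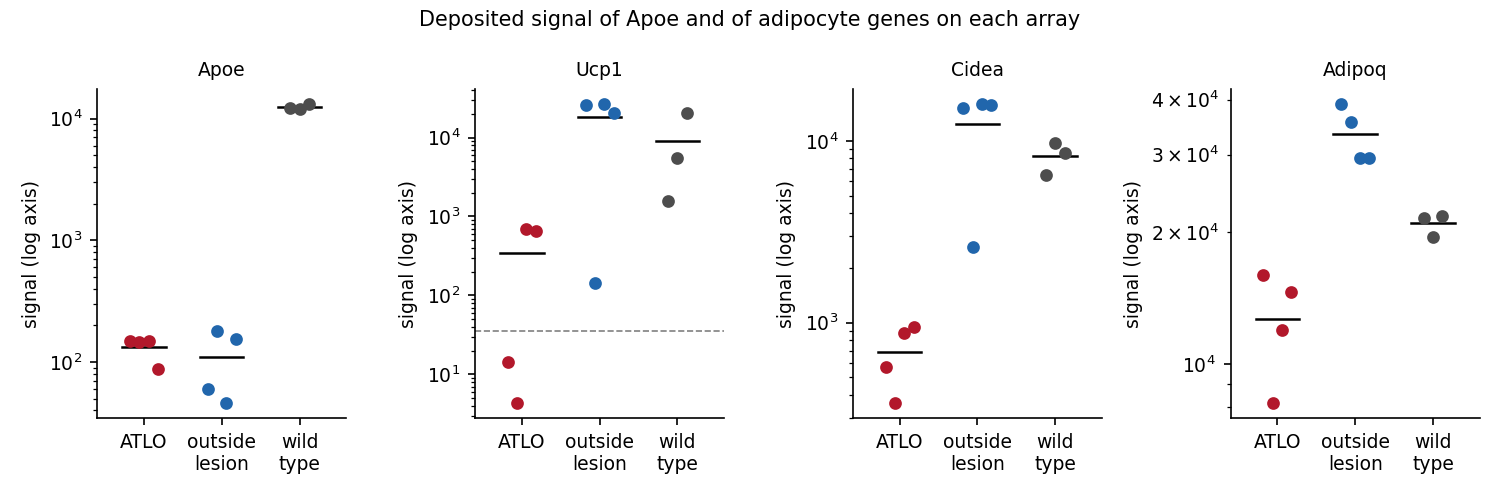
Deposited signals (log axis) of Apoe, Ucp1, Cidea and Adipoq on each of the 11 arrays, with 1 point per array, a line at the group mean and a dashed line at the floor of 35.1 where values lie under it. Apoe lies between 11969 and 13164 in wild type and at most at 179.7 elsewhere, and outside-lesion replicate 2 has Ucp1 at 143 and Cidea at 2590 while its Adipoq lies among those of its group.

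Of 15 endothelial markers, 9 fell (11 adjusted over the list alone; camera adjusted p = 4.22e-05, and adjusted p = 0.192 with an estimated correlation), including the vascular growth factor receptor Kdr (-1.43) and the angiopoietin receptor Tek (-0.98). Of 17 smooth muscle contractile genes, 5 fell, the same number adjusted over the list alone (camera adjusted p = 0.00367, and adjusted p = 0.521 with an estimated correlation). Myh11, smooth muscle myosin, had a log2 change of -1.19 ± 0.41, adjusted p = 0.0417, and Mustn1 a change of -1.14 ± 0.39, adjusted p = 0.0374. Acta2, smooth muscle actin, did not pass the test (log2 change -0.64 ± 0.36, adjusted p = 0.202). Of 8 mast cell markers, 4 fell (4 adjusted over the list alone; camera adjusted p = 0.0104, and adjusted p = 0.380 with an estimated correlation), among them the proteases Mcpt4 (-1.68) and Cpa3 (-1.08). The smooth muscle and mast cell lists did not pass an exact permutation test of the mean log2 value per array (adjusted p = 0.283 and 0.0874), nor did the fibroblast list (adjusted p = 0.0874). The other 12 called lists each reached 0.0495, the smallest adjusted value this test gave.

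Of the nerve-related lists, no gene of the 22 measured neuron and axon genes was called between ATLO and outside-lesion adventitia (median log2 change 1.07, adjusted p = 0.261). Th, tyrosine hydroxylase of noradrenergic neurons, was 584 ± 357 in ATLO and 444 ± 626 outside the lesion (log2 change 1.32 ± 1.01, adjusted p = 0.350). Without outside-lesion replicate 4, whose Th signal was 1368, the neuron list passed at camera's preset correlation as higher in ATLO (adjusted p = 0.00878; with an estimated correlation and all arrays, adjusted p = 0.848). For Schwann cell and myelin genes, 2 of 14 were higher and 1 lower (median log2 change 0.16, adjusted p = 0.826). Of 25 neurotrophin and axon guidance genes, 2 were higher and 3 lower. The receptor Robo1 (1.45) and the semaphorin Sema4d (1.46) were higher. The neurotrophin receptors Ntrk3 (-1.60) and Ntrk2 (-0.84) and the neurite inhibitor Rtn4 (-0.69) were lower. The list was not called (median log2 change -0.10, adjusted p = 0.278). These 5 were named after their values were seen. Of 14 receptors for neurotransmitters and neuropeptides, 2 were higher and 1 lower (median log2 change 0.13, adjusted p = 0.845). The remaining lists were not called by camera, namely neutrophil markers (median log2 change 0.74, adjusted p = 0.278; 3 of 7 higher), lymphatic endothelial markers (median log2 change 0.13, adjusted p = 0.287) and ribosomal proteins (median log2 change 0.24, adjusted p = 0.108). Others were circadian clock (median log2 change -0.33, adjusted p = 0.0881), immediate early genes (median log2 change 0.28, adjusted p = 0.324), cholesterol synthesis and efflux (median log2 change -0.37, adjusted p = 0.161) and skeletal muscle (median log2 change 0.02, exact permutation test of array means adjusted p = 0.886). Of these, the neutrophil, lymphatic endothelial and circadian lists passed the exact permutation test of array means (adjusted p = 0.0495 each).

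**Figure D2:**
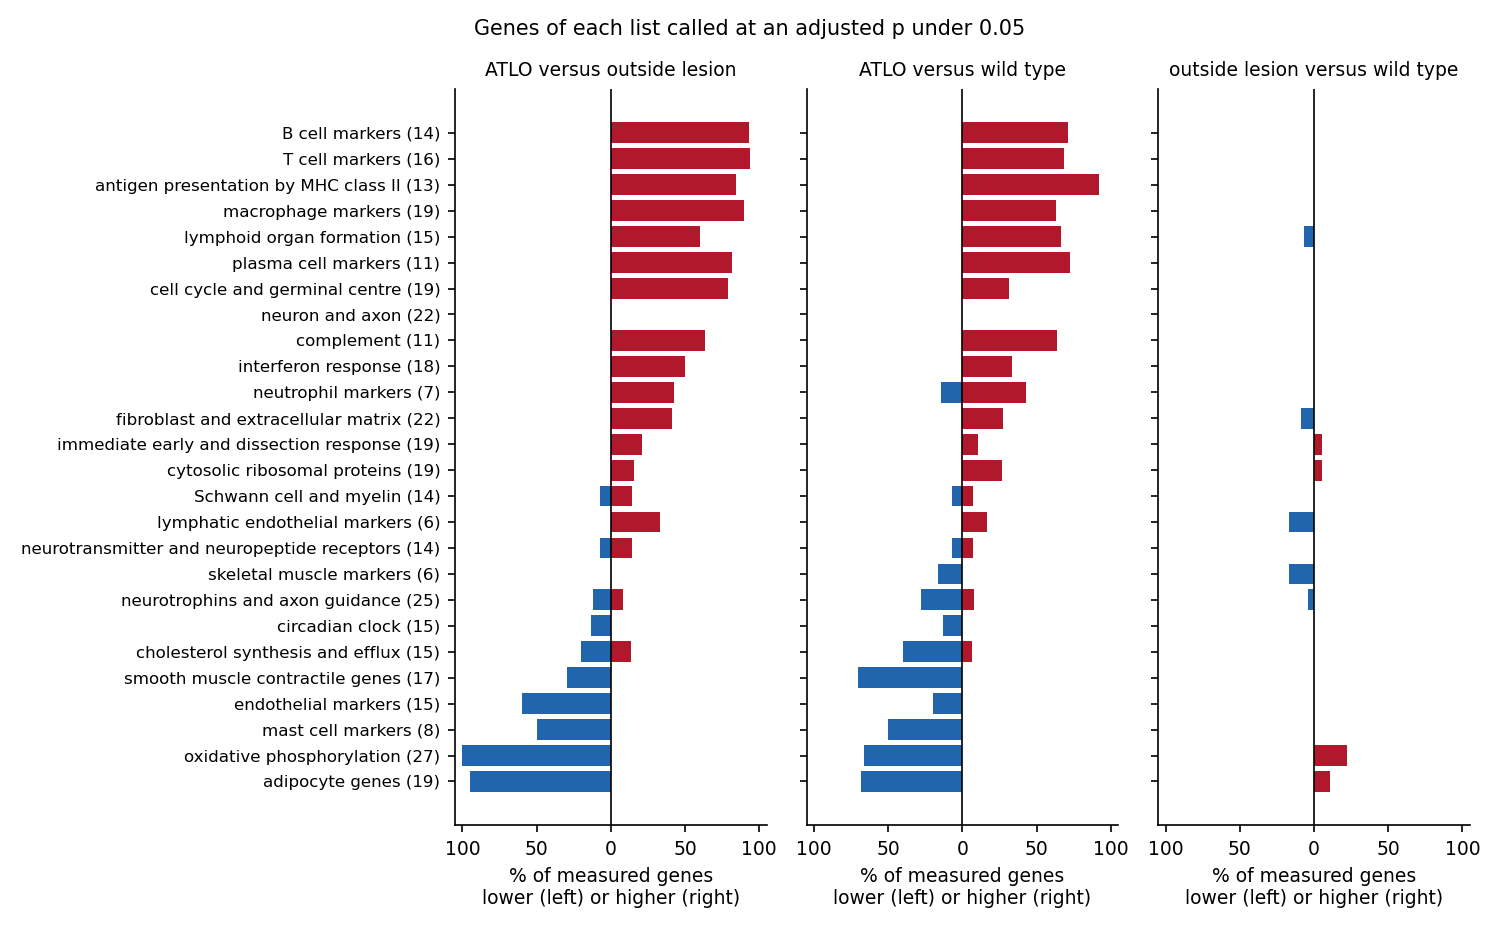
Percent of the measured genes of each of 26 lists (number measured in brackets) called higher, to the right, or lower, to the left, at a limma adjusted p under 0.05, in the 3 comparisons. All 27 oxidative phosphorylation genes were lower in ATLO than outside the lesion, and no neuron and axon gene was called in any comparison.

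Equal array medians in place of the deposited scaling shifted the median log2 change of this comparison by -0.117 and turned the balance of calls, from 56.3% higher to 44.1% higher (1985 higher and 2517 lower). With the actin ratio as a covariate, an alternative added after seeing the data, 2552 probe sets were called. The macrophage, MHC class II and lymphoid organ lists then kept 102%, 99.4% and 97.3% of their median log2 change (15 of 19, 11 of 13 and 9 of 15 genes called). The B cell list kept 70.6% (8 of 14), the T cell list 72.8% (8 of 16), the plasma cell list 88.0% (5 of 11) and the cell cycle list 71.8% (0 of 19). Mast cell markers kept 74.1% (0 of 8), and the smooth muscle list, at 48.0% (0 of 17), was no longer called by camera. Probe sets at least 2-fold apart numbered 2346.

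The comparison of ATLO with wild-type adventitia set diseased tissue against tissue of healthy animals of the same age. Most measured B cell, plasma cell, T cell and macrophage genes were higher, and most adipocyte, respiration and contractile genes lower. None of these 7 lists was called by camera with an estimated correlation (adjusted p between 0.234 and 0.353). Cd72, a B cell surface receptor, was 1374 ± 201 (SD, n = 4) in ATLO and 185 ± 126 (n = 3) in wild type (log2 change 3.09 ± 0.32, adjusted p = 6.25e-05). Cxcl13 was 4629 ± 549.5 against 1338 ± 570.5 (log2 change 1.86 ± 0.27, adjusted p = 4.35e-04). Myh11 was 1393 ± 595 against 4869 ± 551 (log2 change -1.94 ± 0.45, adjusted p = 0.00682). Limma called 4012 of 14988 probe sets, 2001 higher and 2011 lower in ATLO, or 1217 genes higher and 1272 lower. The balance depended on the scaling, with 56.0% of calls higher under equal array medians (2178 higher and 1709 lower) against 49.9% as deposited. Wild-type RNA was extracted with another kit and amplified for 24 h where the other arrays had 68 h, so protocol and genotype cannot be told apart in either comparison with wild type.

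Among named genes without overlap between the groups, the largest rises by limma were those of the immunoglobulin probe sets Igk (log2 change 6.83 ± 0.80, adjusted p = 1.32e-04), Igkv4-72 (4.46), Igkv9-120 (4.29), Iglv1 (3.97) and Igkv6-14 (3.77), whose cross-reading of related genes is open. The least changed probe sets of Igk, Igkv9-120, Iglv1 and, among the falls below, Cyp2b10 were at 0.71, 1.63, 1.80 and -1.58. They were joined by Mmp12 (log2 change at least 4.91, with wild type at the floor, adjusted p = 8.96e-05), Saa3 (log2 change 4.81 ± 0.69, adjusted p = 4.21e-04) and Pou2af1 (log2 change 4.62 ± 0.81, adjusted p = 0.00147). Besides Apoe, the largest falls were those of Ucp1 (log2 change -5.18 ± 1.70, adjusted p = 0.0382), Slc27a2 (-3.75) and Cidea (log2 change -3.66 ± 0.54, adjusted p = 5.12e-04). They were followed by the fatty acid-binding protein Fabp3 (log2 change -3.64 ± 1.18, adjusted p = 0.0360), Pdk4 (-3.25), the cytochrome P450 gene Cyp2b10 (-3.22) and Sost, which encodes the Wnt inhibitor sclerostin (log2 change -3.01 ± 0.48, adjusted p = 7.47e-04). Ucp1 in wild type ranged from 1573 to 20357 over the 3 arrays.

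By list, 10 of 14 B cell markers rose (13 adjusted over the list alone; camera adjusted p = 1.57e-07, and adjusted p = 0.336 with an estimated correlation). Plasma cell markers rose in 8 of 11 cases (9 over the list alone; camera adjusted p = 1.08e-05, and adjusted p = 0.234 with an estimated correlation). T cell markers rose in 11 of 16 cases (13 over the list alone; camera adjusted p = 8.49e-08, and adjusted p = 0.234 with an estimated correlation). Fkbp11 (2.53) and the immunoglobulin joining chain Jchain (2.52) led the plasma cell list, and Il7r (3.05) and the adhesion receptor Cd2 (2.87) the T cell list. Cd3e was 351 ± 93.4 against 64.9 ± 39.5 (log2 change 2.55 ± 0.56, adjusted p = 0.00540). Lymphoid organ genes rose in 10 of 15 cases (10 over the list alone; camera adjusted p = 3.25e-06, and adjusted p = 0.110 with an estimated correlation), with Ltb at 2.91 and Ccr7 at no less than 2.54 on the log2 scale. Macrophage markers rose in 12 of 19 cases (16 over the list alone; camera adjusted p = 1.12e-09, and adjusted p = 0.234 with an estimated correlation), led by Mpeg1 (log2 change 2.49 ± 0.16, adjusted p = 1.97e-06) and the galectin gene Lgals3 (2.35). MHC class II genes rose in 12 of 13 cases (12 over the list alone; camera adjusted p = 7.93e-08, and adjusted p = 0.228 with an estimated correlation), led by Itgax (2.69) and the invariant chain Cd74 (2.03). Of 18 interferon response genes 6 rose (6 over the list alone; camera adjusted p = 0.00510, and adjusted p = 0.234 with an estimated correlation), with Cxcl9 at 2.01 and Cxcl10 at 1.90. Of 11 complement genes 7 rose (7 over the list alone; camera adjusted p = 0.00138, and adjusted p = 0.353 with an estimated correlation), with C6 at 1.68 and C3ar1 at 1.56.

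Cell cycle genes rose in 6 of 19 cases (8 over the list alone; camera adjusted p = 7.61e-05, and adjusted p = 0.353 with an estimated correlation). Mki67 was 924 ± 435 against 279 ± 357, and Rrm2, a ribonucleotide reductase subunit, 647 ± 256 against 234 ± 196. Wild-type replicate 2 held the highest wild-type values, 691 and 460.3. Of 19 ribosomal protein genes, 5 rose (5 over the list alone; camera adjusted p = 7.89e-04, and adjusted p = 0.353 with an estimated correlation), including Rps9 (1.63) and Rps3 (0.78). Of 17 contractile genes, 12 fell (14 over the list alone; camera adjusted p = 1.43e-05, and adjusted p = 0.353 with an estimated correlation). Myocd, the coactivator of smooth muscle genes, was 94.1 ± 35.2 against 379 ± 125 (log2 change -2.03 ± 0.37, adjusted p = 0.00189). For Acta2, the probe set with the highest signal did not pass the test (log2 change -0.65 ± 0.39, adjusted p = 0.236), and its other probe set did (log2 change -1.52, adjusted p = 0.0295). Adipocyte genes fell in 13 of 19 cases (15 over the list alone; camera adjusted p = 2.71e-06, and adjusted p = 0.276 with an estimated correlation), with Adipoq at a log2 change of -0.77 ± 0.24, adjusted p = 0.0300. Oxidative phosphorylation genes fell in 18 of 27 cases (25 over the list alone; camera adjusted p = 1.95e-08, and adjusted p = 0.353 with an estimated correlation), with Uqcrfs1, the Rieske protein of complex III, at -1.41 and Cyc1 at -1.41. Mast cell markers fell in 4 of 8 cases (4 over the list alone; camera adjusted p = 0.0150, and adjusted p = 0.353 with an estimated correlation), with Mcpt4 at -2.04 and Cpa3 at -1.41. Endothelial markers fell in 3 of 15 cases (3 over the list alone; camera adjusted p = 0.0246, and adjusted p = 0.384 with an estimated correlation), with Kdr at -0.95 and Tek at -0.80. Without ATLO replicate 3 the endothelial list was not called (adjusted p = 0.0614). The least changed probe sets of Rrm2 and Rps9 were at a log2 change of 0.64 and 0.52.

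No neuron and axon gene was called against wild type (median log2 change -0.16, adjusted p = 0.796), and Th had a log2 change of -0.19 ± 1.09, adjusted p = 0.916. Schwann cell and myelin genes were not called as a list (median log2 change -0.28, adjusted p = 0.497; 1 higher and 1 lower of 14). Of 25 neurotrophin and axon guidance genes 7 were lower and 2 higher, with the list at median log2 change -0.36, adjusted p = 0.0704. Of 14 neural receptors 1 was lower and 1 higher (median log2 change -0.55, adjusted p = 0.226). The other lists that did not pass by camera were fibroblast and matrix (median log2 change 0.19, adjusted p = 0.0678; 6 of 22 higher), neutrophil (median log2 change 0.91, adjusted p = 0.213) and lymphatic endothelial (median log2 change -0.09, adjusted p = 0.914). Nor did circadian clock (median log2 change -0.40, adjusted p = 0.0777), immediate early (median log2 change 0.28, adjusted p = 0.104), skeletal muscle (median log2 change -0.45, adjusted p = 0.397) and cholesterol (median log2 change -0.46, adjusted p = 0.0678) pass. In the cholesterol list, 6 of 15 genes fell, including the synthesis genes Fdft1 (-1.45) and Sc5d (-1.70), and the efflux transporter Abcg1 (1.45) rose. These 3 were named after their values were seen. Of the 15 lists called by camera, 11 passed the exact permutation test of array means. So did the neutrophil, neural receptor, circadian and cholesterol lists, which camera did not call (adjusted p = 0.0495 each). The mast cell, endothelial, cell cycle and ribosomal lists did not pass it (exact permutation adjusted p = 0.0782, 0.0782, 0.111 and 0.0782).

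**Figure D3:**
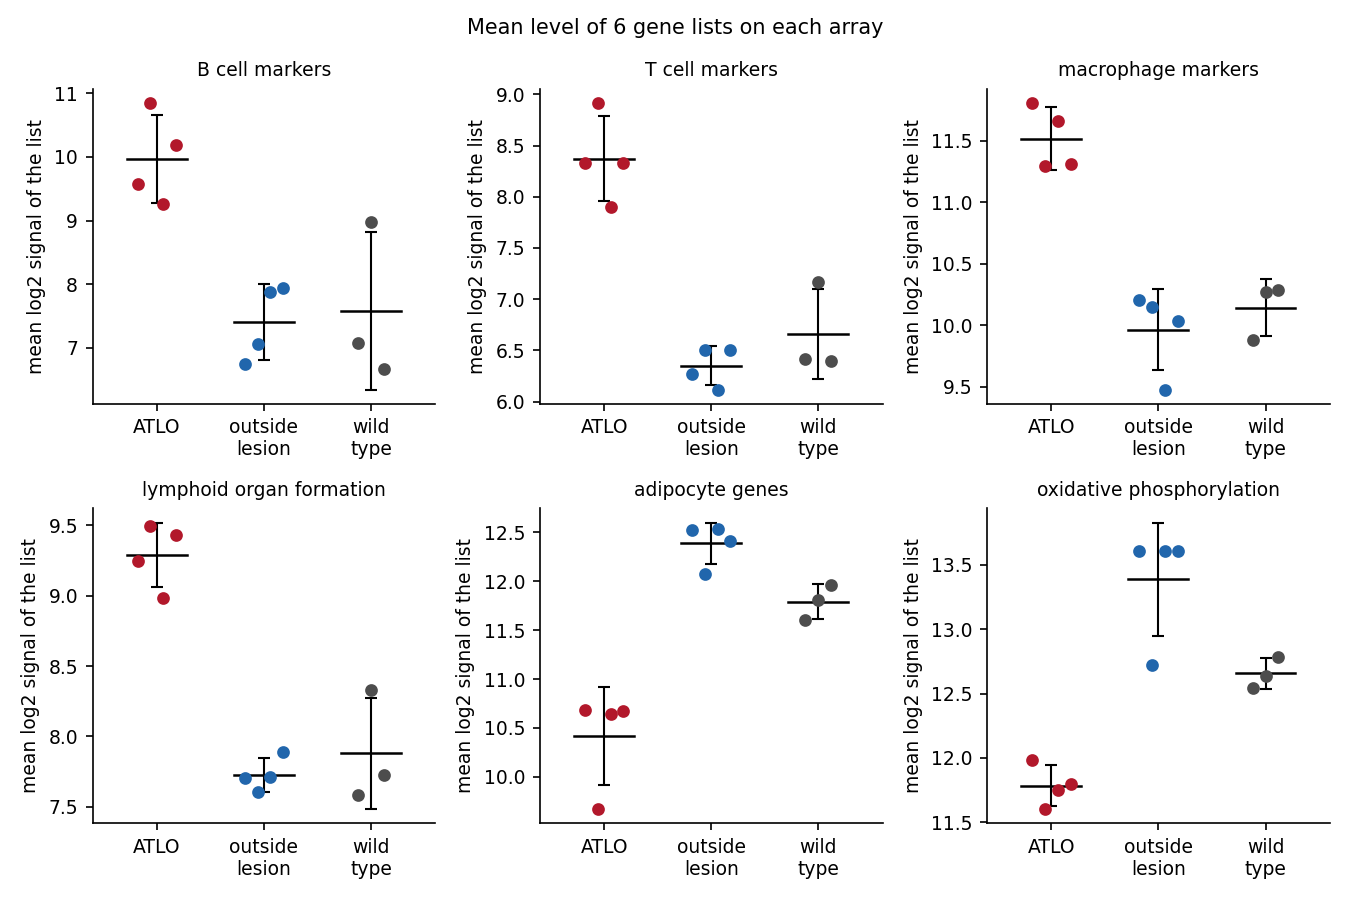
Mean log2 signal per array of 6 gene lists, with 1 point per array (4 ATLO, 4 outside-lesion and 3 wild-type arrays) and the group mean ± SD. The B cell list lies between 9.26 and 10.84 on ATLO arrays, and wild-type replicate 2, at 8.98, is the highest of the other arrays.

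The comparison of outside-lesion with wild-type adventitia asked what differed away from the lesions. Far fewer probe sets were called, 489 of 14988 by limma, with 258 higher and 231 lower outside the lesion (127 genes higher and 152 lower), and 3401 at an unadjusted p under 0.05. Apart from Apoe, the largest change of a named gene was in Igkv8-30, an immunoglobulin light chain probe set read at 29442 ± 6459.6 (SD, n = 4) against 2711 ± 873 (n = 3) (log2 change 3.46 ± 0.43, adjusted p = 0.00336), which may read related light chains. Rgcc, a regulator of the cell cycle, was 16537 ± 2164 against 4822 ± 1423 (log2 change 1.81 ± 0.21, adjusted p = 0.00254). Npnt, the matrix protein nephronectin, was 235 ± 164 against 1292 ± 46.9 (log2 change -2.71 ± 0.48, adjusted p = 0.0177). Ncam1, the neural cell adhesion molecule, was 158 ± 129 against 936 ± 646 (log2 change -2.72 ± 0.64, adjusted p = 0.0392).

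The other genes with the largest rises among those without overlap, as log2 change by limma, were Gga1 (2.18), Ptpn23 (2.09), Slc25a26 (2.03), Atp5md (1.69), Myo5c (1.67) and Mapre3 (1.63), with adjusted p between 0.0147 and 0.0483. Slc25a26 is a mitochondrial carrier, Atp5md a subunit of ATP synthase, Myo5c a myosin and Mapre3 a microtubule-binding protein. Those with the largest falls were Osbpl5 (-2.51), Sost (-2.14), Marco (-2.11), Erdr1 (-2.11) and Eef1a2 (-2.04), with adjusted p between 0.0148 and 0.0489. Marco is a scavenger receptor of macrophages and Eef1a2 a translation elongation factor of neurons and muscle. The least changed probe sets of Slc25a26, Rgcc, Ncam1 and Npnt were at 0.31, 0.85, -1.26 and -0.60. Of the 27 oxidative phosphorylation genes, 6 rose (22 adjusted over the list alone; camera adjusted p = 1.95e-17, and adjusted p = 0.532 with an estimated correlation), with Uqcrc2 at 14108 ± 4947 against 5347 ± 857 and Cycs at 22050.4 ± 6577 against 8964 ± 950.3. The list mean of outside-lesion replicate 2, 12.72 on the log2 scale, lay inside the wild-type range (12.55 to 12.79), and the other 3 outside-lesion arrays were at 13.61. Of 19 adipocyte genes, 2 rose (6 adjusted over the list alone; camera adjusted p = 4.59e-07, and adjusted p = 0.532 with an estimated correlation), the glycerol channel Aqp7 (log2 change 1.18 ± 0.24, adjusted p = 0.0269) and the lipase Pnpla2 (log2 change 1.04 ± 0.24, adjusted p = 0.0382). Those of Aqp7, Pnpla2 and Uqcrc2 that changed least were at 0.22, 0.20 and 0.49. Adipoq did not pass (log2 change 0.67 ± 0.24, adjusted p = 0.132). The endothelial list was called (camera adjusted p = 0.00454, and adjusted p = 0.679 with an estimated correlation) with 0 of its 15 genes called, and was not called without outside-lesion replicate 2 (adjusted p = 0.0919). None of these 3 lists passed the exact permutation test of array means (adjusted p = 0.371, 0.297 and 0.545), which no list passes unless 15 of 26 reach its smallest p.

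No gene in the fixed lists of B cell, plasma cell, T cell, macrophage or MHC class II genes, which hold neither Marco nor Igkv8-30, was called between outside-lesion and wild-type adventitia (list adjusted p by camera = 0.942, 0.631, 0.531, 0.669 and 0.655). Cd3e (log2 change 0.30 ± 0.56, adjusted p = 0.779), Cxcl13 (log2 change -0.59 ± 0.27, adjusted p = 0.211), Acta2 (log2 change -0.01 ± 0.39, adjusted p = 0.992, and -1.20 on its other probe set) and Th (log2 change -1.52 ± 1.09, adjusted p = 0.422) did not pass limma's test. In the lymphoid organ list 1 gene fell, Tnfsf13b, the B cell survival factor (-0.74, list adjusted p = 0.717). The neuron and axon list was not called (median log2 change -1.22, adjusted p = 0.0697, and adjusted p = 0.954 with its estimated correlation of 0.859). At camera's preset correlation it passed, as lower outside the lesion, when any 1 of 3 particular arrays was left out. These were wild-type replicate 2 (adjusted p = 1.95e-06), wild-type replicate 3 (0.0471) and outside-lesion replicate 4 (8.75e-05), while without wild-type replicate 1 it turned upward (adjusted p = 0.554). At the preset correlation it was also called lower with equal medians, quantile normalization, the replicate block and the actin covariate. Schwann cell genes (median log2 change -0.45, adjusted p = 0.209), axon guidance genes (median log2 change -0.41, adjusted p = 0.465; Unc5c lower at -0.74) and neural receptors (median log2 change -0.58, adjusted p = 0.0697) did not pass. Lists of interferon response (median log2 change -0.27, adjusted p = 0.113), complement (median log2 change -0.20, adjusted p = 0.916), and mast cells (median log2 change -0.14, adjusted p = 0.991) did not pass. Neither did those of neutrophils (median log2 change 0.03, adjusted p = 0.916), smooth muscle (median log2 change -0.75, adjusted p = 0.0528) and fibroblasts (median log2 change -0.52, adjusted p = 0.0578; Pdgfra at -1.28 and Lum at -1.20 lower). Nor did lymphatic endothelium (median log2 change -0.35, adjusted p = 0.0727; Pdpn lower), cell cycle (median log2 change -0.34, adjusted p = 0.609), ribosomal proteins (median log2 change 0.31, adjusted p = 0.0538; Rps9 higher at 1.32) and circadian clock (median log2 change -0.01, adjusted p = 0.916) pass. The same held for immediate early genes (median log2 change 0.02, adjusted p = 0.452; Socs3 higher at 1.24), cholesterol (median log2 change -0.37, adjusted p = 0.713) and skeletal muscle (median log2 change -0.49, adjusted p = 0.465; Tcap lower at -1.20). Tnfsf13b and the genes in brackets are the called members of lists that were not called, and were named after their values were seen.

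This comparison depended on the scaling and on single arrays. Equal array medians shifted its median log2 change by 0.172 and gave 87.3% of calls higher (557 higher and 81 lower), and quantile normalization 69.0% (301 and 135), against 52.8% as deposited. The count fell to 21 without wild-type replicate 2 and rose to 886 without outside-lesion replicate 2. Of its 20 called named genes, 3 (Apoe, Igkv8-30 and Rgcc) were called under every alternative.

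**Figure D4:**
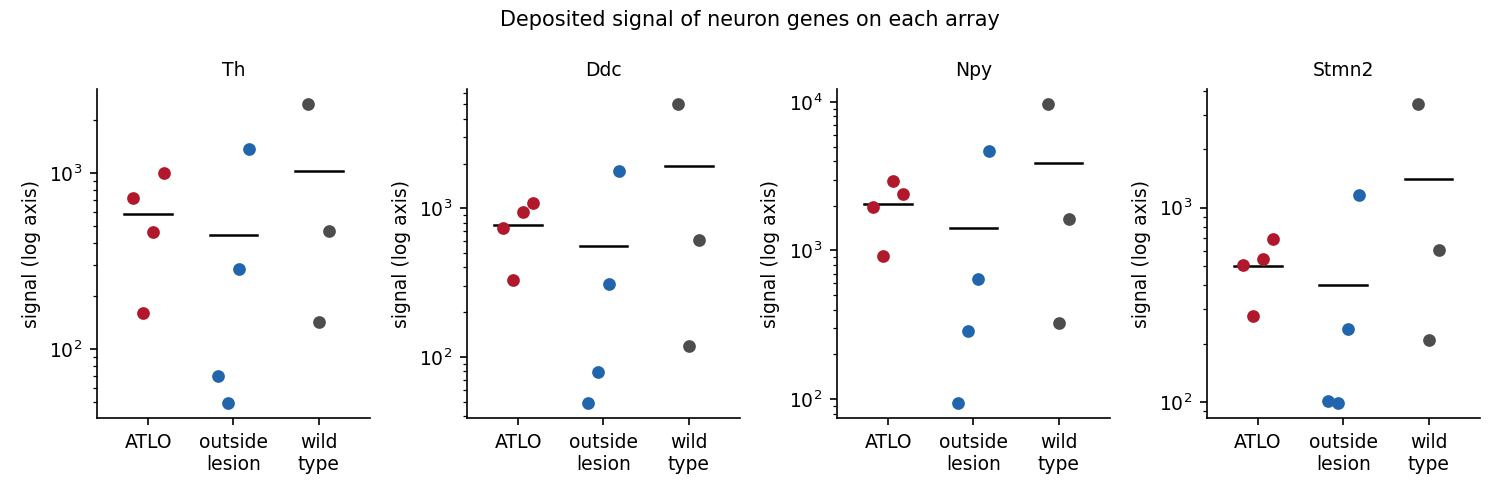
Deposited signals (log axis) of the noradrenergic and neuronal genes Th, Ddc, Npy and Stmn2 on each of the 11 arrays, with 1 point per array and a line at the group mean. The arrays of a group spread widely, with Th from 49.3 to 1368 outside the lesion and from 142 to 2462 in wild type.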

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

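The comparison of brown with general adipocyte genes and the percent of the adipocyte change kept under the covariate were chosen after the results were seen, as was the use of the actin ratio as a covariate. Each group of 4 arrays was searched for an array far from the other 3, and 27 of 228 groups (11.8%) had one. The limit used flags about 1 in 20 groups of normally distributed values. Many of the genes and lists searched moved together, and some values lay at the floor. The 11.8% is therefore not read against that rate. Groups of 3 were not searched.

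Outside-lesion replicate 2 accounted for 9 of these, each a gene or list of fat and respiration on which it lay under the other 3 arrays. It read Ucp1 at 143 (others 20513 to 26624), Slc27a2 at 46.3 (1516 to 1984), Cidea at 2590 (printed to more digits, 2589.6; others 15072 to 15942), Pdk4 at 992, Cox8b at 3658, Coq8a at 748, Cyc1 at 6654 and Uqcrc2 at 6804, and its oxidative phosphorylation mean was 12.72 on the log2 scale (others 13.61 to 13.61). Its Adipoq signal, 35535, lay inside its group. Its mean log2 value of general adipocyte genes, 13.32, was the highest of its group (others 12.97 to 13.28). That of brown adipocyte genes, 8.33, was the lowest (others 11.01 to 11.32).

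The pattern that most invites a second look is the lower level of adipocyte and respiration genes in ATLO. A smaller share of fat cells of every kind would lower brown and general adipocyte genes by the same factor. That holds only if fat cells alone made these genes, which was not tested. Brown genes (11 measured, 3 of them also in the adipocyte list) had a median log2 change of -3.37 and general genes (14, all in that list) of -1.55, a difference of -1.82 with a permutation p over genes of 0.00123, but genes are not independent and Dio2, a brown gene, was at 0.15. In the test over arrays that replaced it, the brown minus general mean was -4.17 ± 0.59 (SD, n = 4) in ATLO and -2.67 ± 1.55 (n = 4) outside the lesion, with an exact permutation p of 0.143; outside-lesion replicate 2, at -4.99, lay beside the lowest ATLO array (-4.98), so in this comparison a uniform loss of fat and a loss of mainly brown fat cannot be told apart. Against wild type the arrays did not overlap (-4.98 to -3.70 in ATLO and -3.30 to -1.62 in wild type). Median log2 changes were -2.60 for brown and -0.76 for general genes. A uniform loss would not give this if fat cells alone made these genes, but the protocol changed with genotype. General genes differed among themselves there. Slc2a4 lay at 418 to 755 in ATLO and 2062 to 2389 in wild type. Fabp4, the highest signal of every wild-type array, overlapped (13919 to 47631 and 27380 to 34091). Whether the highest signals were compressed or other cells made general genes was not tested, so a uniform loss is not excluded there. RNA integrity was checked with the actin ratio, 4.61 in ATLO and 8.71 outside the lesion. The Gapdh ratio (1.93 and 1.74) did not show this gap and was not tried as a covariate, so integrity itself is not excluded. The actin ratio as the whole cause is argued against for respiration genes, which kept 89.8% of their median change with it as a covariate (26 of 27 still called). The adipocyte list kept 78.3% (11 of 19 still called), which stays open because it lies between the bounds set for either reading. The share of fat in the dissected region, a difference between the tissues that the labels name, was not tested apart from these genes.

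The other results were spread over arrays and are given as values. ATLO replicate 4 had Slpi at 2618 (others 12872 to 17172), Creld2 at 2261 (5838 to 6801), Apoe at 86.9 (147 to 150.2) and Slc27a2 at 39.7, just over the floor of 35.1. ATLO replicate 3 had Ccr7 at 139.9 (others 221 to 240.2) and a skeletal muscle list mean of 7.74 on the log2 scale (5.88 to 6.14). ATLO replicate 2 had Top2a at 777 (463 to 477) and an adipocyte list mean of 9.67 (10.64 to 10.68). ATLO replicate 1 had Cycs at 6703 (4277 to 4410.4) and Marco at 62.9, where the others lay under the floor. Outside-lesion replicate 1 had Frzb at 90.8 (15.1 to 40.2), Jchain at 2544 (6343 to 7553), Rgcc at 19756 (15227 to 15856) and a skeletal muscle list mean of 7.26 (6.02 to 6.13). Outside-lesion replicate 4 had Cd3d at 127.8 (11.9 to 43.3), Gga1 at 63.3 (240.5 to 292.5) and an MHC class II list mean of 9.31 (8.90 to 8.97). Outside-lesion replicate 3 had Cd74 at 3420 (more exactly 3419.7; others 5500 to 5943).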

How the results depend on the processing

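The actin covariate and the exact test of list means were chosen after the data were seen. Of the called named genes, 36 of 46 between ATLO and outside-lesion, 35 of 46 between ATLO and wild type and 3 of 20 between outside-lesion and wild type stayed called in the same direction under every alternative. Counts of called probe sets for ATLO against outside-lesion (4777) stayed within 1.5 times except with a 2-fold threshold, which is stricter by construction (2346), and the actin covariate (2552). For ATLO against wild type (4012) only the 2-fold threshold (2009) moved it so far. For outside-lesion against wild type (489) the count was 301 with no filter, 202 with only the compared groups, 1530 with array weights, 248 with no intensity trend, 238 with a 2-fold threshold and 86 with the actin covariate; the cause was not tested, except that fewer arrays enter with only the compared groups. Leaving out arrays gave 4003 to 4634 (ATLO against outside-lesion), 2740.0 to 3548 (ATLO against wild type) and 21 to 886 (outside-lesion against wild type), the last with 203, 886, 164 and 112 without outside-lesion replicates 1 to 4 and 106, 21 and 27 without wild-type replicates 1 to 3.

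The replicate number as a block gave 4744 called probe sets for ATLO against outside-lesion, 3106 for ATLO against wild type and 27 for outside-lesion against wild type, on fewer arrays in the comparisons with wild type. The numbers are not read as pairs, because no label says that same-numbered arrays share an animal. Deviations of same-numbered arrays from their group means correlated at 0.04 to 0.15, 0.005 to 0.27 and -0.18 to 0.12. For ATLO against outside-lesion the mean was 0.10, against -0.03 for other pairs. It was 0.16 against -0.05 for ATLO against wild type and -0.01 against 0.004 for outside-lesion against wild type. Arrays of different genotypes cannot share an animal, so this measure neither shows nor excludes pairing between ATLO and outside-lesion arrays. The array with the same number was the best match in 2 of 4, 3 of 3 and 2 of 3 cases. All camera calls were lost with an estimated correlation (0 lists in each comparison, from 15, 15 and 3). Apart from it, 12 of 15, 11 of 15 and 0 of 3 called lists stayed called in every alternative. Besides the exact test, calls ended with array weights (mast cell and smooth muscle in ATLO against outside-lesion, mast cell in ATLO against wild type), the actin covariate (smooth muscle in ATLO against outside-lesion), and without ATLO replicate 3 (endothelial against wild type) or outside-lesion replicate 2 (endothelial in outside-lesion against wild type). For outside-lesion against wild type, 3 lists became 6 with quantile normalization, 7 with equal medians, 6 with only the compared groups, 8 with the block, 5 with array weights, 6 with no intensity trend, 5 with averaged probe sets, 8 with the actin covariate, 0 in the exact test of list means and 4 to 7 without an array; the cause was not tested.

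No result called in the primary analysis changed sign; of the uncalled ones that did, the genes named in every comparison and the neuron list are given. Th in ATLO against wild type (log2 change -0.19) was 0.51 with array weights, 0.0151 with the actin covariate and between -1.17 and 0.89 without an array. The neuron list in ATLO against wild type (adjusted p = 0.796) turned upward without wild-type replicate 1 at an adjusted p of 0.0321, with 0.0321 to 0.839 over left-out arrays, and was called lower without wild-type replicate 2 (0.0323), both at the preset correlation. It also turned upward without ATLO replicate 2 (0.808) and with array weights. In outside-lesion against wild type it turned upward without wild-type replicate 1 (0.554) and with array weights. Acta2 in outside-lesion against wild type (-0.01) was 0.16 with equal medians, 0.16 with the block and between -0.23 and 0.23 without an array, and Cd3e (0.30) was between -0.14 and 0.77. About 20% of signals lay at the floor (17.8% to 22.1% per array), and changes under it are not measured.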

Other observations

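The protocol test, the actin covariate, the breakdown of the calls it ended and the count of other splits for the exact list test were chosen after the results were seen. Immunoglobulin light chain probe sets differed between arrays of the ATLO group. Igkv6-14 was read at 529.5, 3134, 8820.3 and 383 on ATLO replicates 1 to 4, Igkv4-72 at 4879, 2582, 897 and 84.9, and Igkv9-120 at 4457, 8035, 2107 and 2136. Igkv8-30 lay between 21300.2 and 36042 outside the lesion, where B cell markers were not called against wild type. Wild-type replicate 2 held more lymphocyte signal than the other wild-type arrays. Its B cell list mean was 8.98 (others 6.67 and 7.08), its T cell list mean 7.16 (others 6.39 and 6.42) and its Pou2af1 signal 1455. Outside the lymphocyte lists, it also had a cell cycle mean of 8.47 (others 7.14 and 7.17) and Slpi at 11359 (others 185 and 234). Socs3, a feedback inhibitor of cytokine signalling, rose in ATLO against outside-lesion (log2 change 2.33, limma adjusted p = 4.88e-05) and wild type (3.57, adjusted p = 2.05e-05), as did the calgranulin S100a9 (2.28 and 3.23, adjusted p = 0.0406 and 0.0135); these genes were chosen after their values were seen.

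Neuron genes varied together between arrays of one group. The neuron and axon list had a within-group SD of 1.37 on the log2 scale, the largest of the 26 lists, against 0.437 for Schwann cell genes, and Npy was read at 9676 on wild-type replicate 1 and 326 on wild-type replicate 2. A candidate explanation is ganglion or nerve tissue in some dissections. It predicts that neuron genes outside the list follow it, and 18 such genes, of which 1 is in another fixed list and some, such as Map1b, are also made by other cells, had a median within-group correlation of 0.815 with the list mean (0.33 to 0.98 over genes, above all of 10000 random lists, whose highest median was 0.49). Any cause that moves neuron genes together would give this, so the result does not single out ganglion or nerve tissue. RNA integrity as the cause stays open, with a correlation of 0.179 between the list's deviations and those of the actin ratio over 11 arrays (Spearman's rho 0.2, permutation p = 0.467, r = -0.02 without the 2 arrays farthest from the median), whose upper bound of 0.754 is above the limit set beforehand. No biological explanation within a group was tested, since the labels name no difference between its arrays.

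The 489 probe sets called between outside-lesion and wild-type adventitia have a technical rival in the extraction and labelling protocol, which changed with genotype. No wild-type array was made with the protocol of the other arrays (0 of 3), so protocol and genotype cannot be told apart, except for Apoe itself, which is disrupted. RNA integrity was checked with the actin ratio only and the Gapdh ratio was not tried, so integrity itself is not excluded. Whether the actin ratio was the whole cause stays open. The covariate's slope is fitted to the spread within groups, and calls favour probe sets where that spread is small. A small shift was thus favoured by the choice of probe sets. With the actin ratio as a covariate the called probe sets kept 95.9% of their median log2 change (0.99 before and 0.95 after). All 489 kept their sign. Of them, 78 were still called, and of the 411 others 152 kept an unadjusted p within the limit of the first fit and were lost only to the adjustment, and 259 did not, with a median log2 change over the 411 of 0.95 before and 0.88 after and a median standard error of 0.21 before and 0.23 after. Between ATLO and outside-lesion the median change of called probe sets was 0.99 before and 0.88 after, with the standard error at 0.21 and 0.26.

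All 35 splits of the arrays of each comparison into groups of the same sizes were tried. For called probe sets, only the real split, 1 of 35, gave as many in each comparison. That is the smallest share 35 splits can give, so chance is made less likely but is not excluded. Splits of arrays also say nothing about arrays that might share an animal. For outside-lesion against wild type another split came close, and leaving out 1 array moved the count between 21 and 886. The real counts were 4777 (highest other 0), 4012 (highest other 92) and 489 (highest other 412, from the split that set outside-lesion replicate 2 with the wild-type arrays). In other splits a real difference between the groups would enter the spread within groups and lower the calls. Their counts therefore do not show how many probe sets chance alone would call. For lists called by camera, chance cannot be excluded, as 10 of 35 splits gave as many as the 15 of ATLO against outside-lesion (highest other 19), 10 of 35 as many as the 15 of ATLO against wild type (highest other 19), and 35 of 35 as many as the 3 of outside-lesion against wild type (highest other 15, several times the real count). In both ATLO comparisons, every other split with 15 or more lists had 3 ATLO arrays on one side. Such splits keep part of the real difference, so their counts do not show what chance alone would give. Splits with 2 ATLO arrays on each side gave at most 13 lists against outside-lesion and 14 against wild type. A structure of the samples other than the groups, or a preset correlation of 0.01 where those estimated reached 0.859, would also raise such counts, and neither was tested here. For the exact test of list means the count of splits says nothing about chance, because its outcome was fixed beforehand. A split passes any list only with 15 of 26 lists at the smallest p of 0.0286, and where the real split holds 15, at most 11 are left for another. The counts were 1 of 35 splits for the 15 lists of ATLO against outside-lesion (highest other 0), 1 of 35 for the 15 of ATLO against wild type (highest other 0), and 35 of 35 for outside-lesion against wild type, where 0 lists passed (highest other 0) and 3 were at the smallest p.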
